A study of Homo sapiens with 7 samples.

How the data were processed

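The peak lists of H3K79succ in U251 cells, Gcn5 in U251 cells, α-KGDH in U251 cells with V5-OGDH, and H3K79succ in shGcn5 U251 cells were used as deposited. The 3 input libraries were not used here by themselves. The submitters' processing notes name CASAVA, Bowtie2, MACS2 and the build hg19, without versions, parameters or roles. Which input served as the control of each list, and the thresholds of the calls, are not given in the sources used here.

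Each region in the lists the authors deposited has a fold, a ratio of the summit over the caller's local background, a −log10 p and a −log10 q at the summit, a score, and the position of the summit. The deposited score was compared with the other columns: it is 10 times −log10 p in the H3K79succ, Gcn5 and α-KGDH lists of the authors, and 10 times −log10 q in the shGcn5 list, for 100% of regions. The lowest −log10 p was 3.03, 3.02, 4.07 and 6.51 in the H3K79succ, Gcn5, α-KGDH and shGcn5 lists, so the authors' lists were not called at one threshold. Folds and scores were used to describe, rank and filter regions within a list.

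Samples were grouped by their titles in the labels, which give 1 library per group and no replicates. Overlapping rows of a list were to be merged, but none overlapped, so the numbers of rows and regions are equal. A region was counted as overlapping another list when it shared at least 1 base pair with a region there. The expected overlap came from 1000 copies of the other list, each shifted circularly within each chromosome between the first and last region of any list. The permutation p is one-sided, for an overlap at least as large, has 0.001 as its smallest value, and was adjusted by the Benjamini-Hochberg method over 12 overlaps. These 12 count each pair of lists in both directions, so they are not independent. Shares have 95% exact (Clopper-Pearson) binomial intervals over regions, which cover counting error only and say nothing of the spread between cultures. Medians were compared by a two-sided permutation test with 100000 resamples, and shares of regions by two-sided Fisher's exact tests; odds ratios have Woolf intervals, or Mantel-Haenszel intervals where stratified. Regions are not replicates of a condition, and neighbouring regions are not independent, so these tests describe the lists and their p-values can be too small. No difference between shGcn5 and U251 cells was tested as a condition.

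The lists hold no read depth. Under the formulas of MACS2, in which the fold is the pileup plus 1 over the background plus 1 and the p-value is a Poisson tail, a whole pileup was searched that gives both deposited values within 0.0002 of −log10 p. It was found for 100% of regions in each list. In simulated peaks the right pileup was recovered in 100% of cases, and a disturbed p-value was matched in 0.100%. The lowest background of a list, its floor, is taken as fragments times fragment length over genome size. It was 1.04 times as high in the shGcn5 list as in the U251 H3K79succ list, 0.860 times for Gcn5 and 1.19 times for α-KGDH. The median pileup was 18 fragments for H3K79succ, 16 for Gcn5, 19 for α-KGDH and 23 for shGcn5, which sets the precision of a single region's fold.

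The overlap code was tested on simulated data. For H3K79succ with Gcn5, unrelated lists gave 0.973 times the expected overlap on average over 100 pairs, with a p at or under 0.05 in 1 pair, and all planted overlaps were recovered. For α-KGDH with Gcn5 the same test gave 1.17 times and 3 pairs.

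Before the data were examined, these alternatives were fixed: an overlap of at least 50% of the shorter region, regions within 500 bp, −log10 q of at least 5, a fold of at least 5, rows left unmerged, chromosomes 1 to 22 and X, the top 1% of fold left out, random placement in place of circular shifts, and stratification by 5 quintiles of fold. Added after seeing the data were one −log10 p minimum of 6.51 for every list, the lowest of the shGcn5 list; moves of each region by up to 50 kb; further settings for the median difference; the top 1% left out for the odds ratio with Gcn5; and both stratified odds ratios with α-KGDH.

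Regions were named by a rule fixed beforehand for a series without an hg19 annotation: the 5 regions of highest fold in each list, and the 10 regions of highest H3K79succ fold in the H3K79succ, Gcn5 and α-KGDH lists together, with no gene names. Other regions named in the closing part were chosen after their values were seen. The gene table used here is on another build, and coordinates were not converted between builds. Shares of regions at transcription start sites, tests among promoters and counts of fixed gene lists were planned for an hg19 annotation and were therefore not run. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.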

Results

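Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in U251, an established human glioblastoma cell line. The study mapped succinylation of lysine 79 of histone H3 (H3K79succ), the acetyltransferase Gcn5 (KAT2A), and the α-ketoglutarate dehydrogenase complex (α-KGDH), the enzyme of the citric acid cycle that makes succinyl-CoA. H3K79succ was mapped in U251 cells and in a stable U251 line named for a short hairpin RNA against Gcn5 (shGcn5). Gcn5 was mapped in U251 cells, and α-KGDH in U251 cells with V5-OGDH, named for an epitope-tagged OGDH subunit of the complex. The series holds 7 libraries with 1 library per group, 3 of them inputs, and a peak list for each of the 4 immunoprecipitations was analysed. There were no replicates, so no difference between conditions could be tested, and every test below compares regions within or between these lists. Fold enrichment is the authors' value at a region's summit over the caller's local background, and positions are in hg19, counted from 1. No hg19 gene annotation was used here, so regions carry no gene names.

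H3K79succ occupied 17107 regions in U251 cells, with a median width of 259 bp (quartiles 216 to 369 bp) and 5.83 Mb in all. The median fold enrichment was 3.44 (quartiles 3.07 to 3.98) and the highest 11.2. The regions of highest fold enrichment lay on chromosome 11, 11268027 to 11268644 (fold 11.2), chromosome 1, 156084548 to 156085866 (fold 10.8), chromosome 17, 38278581 to 38279747 (fold 10.8), chromosome 19, 47613866 to 47615492 (fold 10.8) and chromosome 20, 49546812 to 49547717 (fold 10.0). Gcn5 occupied 12505 regions with a median width of 246 bp, 3.98 Mb in all, and a median fold enrichment of 3.38 (quartiles 3.06 to 3.82). α-KGDH occupied 249 regions, with a median width of 262 bp and a median fold enrichment of 3.83 (quartiles 3.43 to 4.29). Of the α-KGDH regions, 208 (83.5%) had a q-value at or under 0.05, against 16570 (96.9%) of the H3K79succ regions and 11628 (93.0%) of the Gcn5 regions. The background floor recovered from the fold and p-values, which scales with the number of fragments times their length, was 3.09 fragments for H3K79succ, 2.66 for Gcn5, 3.66 for α-KGDH and 3.22 for H3K79succ in shGcn5 cells.

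The overlap of H3K79succ with Gcn5 asks whether the succinylated histone lies where Gcn5 is bound. Of the 17107 H3K79succ regions, 482 (2.82%, 95% exact binomial interval 2.58 to 3.08%) overlapped a Gcn5 region, and 479 of 12505 Gcn5 regions (3.83%, interval 3.50 to 4.18%) overlapped H3K79succ. The strongest region of both lists was the same place, on chromosome 11, where the Gcn5 region ran from 11267975 to 11268656 with a fold enrichment of 15.9 and a pileup of 95 fragments. The next Gcn5 regions by fold enrichment lay on chromosome 15, 86439811 to 86440836 (fold 14.2), chromosome 20, 2450975 to 2451479 (fold 12.8), chromosome 10, 69524102 to 69524489 (fold 12.6) and chromosome 8, 124169316 to 124169706 (fold 12.3), and each overlapped an H3K79succ region. Most regions of either list had no partner in the other.

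Circular shifts of the Gcn5 regions along their chromosomes gave 59.0 overlapping H3K79succ regions on average and at most 93 in 1000 copies, so the observed 482 was 8.16 times the expected number (permutation p = 0.001, the smallest the copies can give, and 0.001 adjusted over 12 overlaps). When each Gcn5 region was instead moved by up to 50 kb, the expected number was 134 and the excess 3.60 times. The excess over these local moves was seen at short distances: 4.17% of H3K79succ regions lay within 500 bp of a Gcn5 region against 1.83% after local moves. Within 5000 bp the share was 9.60% against 9.32%, and within 20000 bp it was 21.5% against 23.5%. Independent moves also scatter groups of neighbouring Gcn5 regions, which can raise the expected share at larger distances. The distance at which the excess ends is therefore not settled. Local moves keep the density of Gcn5 regions on scales above the moves, so the larger excess over circular shifts includes a regional part. The share of H3K79succ regions with Gcn5 was 1.68% among regions with −log10 q of at least 5 in both lists, and 1.57% under one p-value minimum for every list. The share of Gcn5 regions with H3K79succ was 5.64% and 2.62% there. The Gcn5 list shrank to 976 and 4697 regions at these thresholds. No expected overlap is given at these sizes, so the shares do not show a weaker or stronger association.

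**Figure D1:**
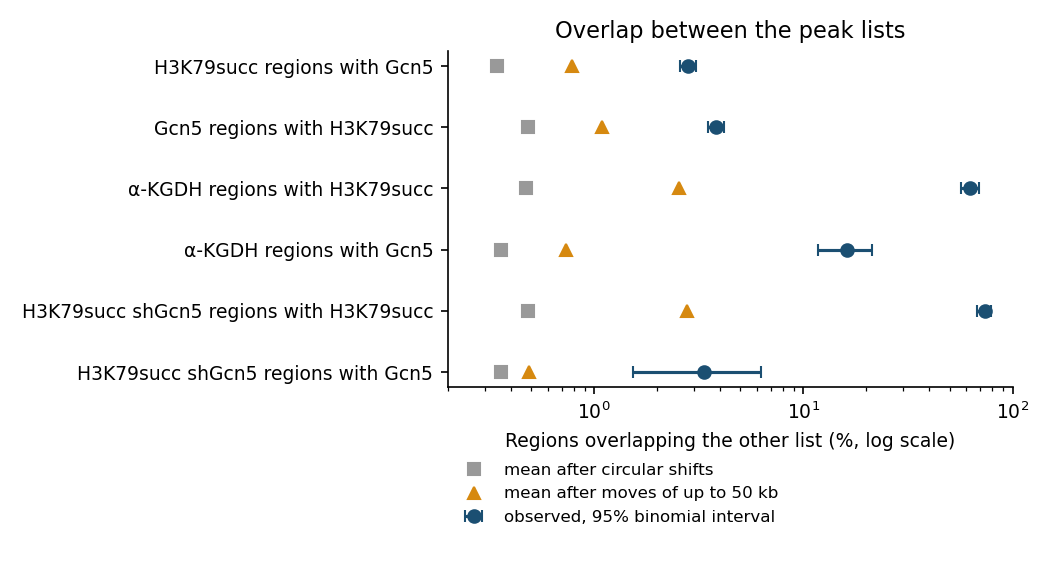
Share of the regions of one list that overlap a region of another, in percent on a log axis; circles are observed shares with 95% exact binomial intervals, squares the mean after circular shifts, triangles the mean after moves of up to 50 kb. The share of α-KGDH regions with H3K79succ (62.7%) and with Gcn5 (16.1%) lay far above both expectations, and H3K79succ regions with Gcn5 (2.82%) lay above them by less.

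The median fold enrichment of H3K79succ regions was 3.43 with Gcn5 and 3.45 without, a difference of -0.0146 (two-sided permutation test with 100000 resamples, p = 0.678), while the means, 3.84 and 3.64, differed by 0.197 in the other direction. The direction depended on the threshold: among regions past −log10 q of 5, those with Gcn5 had the higher median by 0.391 (permutation p = 0.0036), and under one p-value minimum by 0.743. Within the Gcn5 list the overlap was more frequent at the top. Of the 125 Gcn5 regions in the top 1% by fold enrichment, 43 (34.4%) overlapped H3K79succ, against 436 of the other 12380 (3.52%), an odds ratio of 14.4 (two-sided Fisher's exact test, p = 6.9e-30), a split chosen after the values were seen. These 43 regions were narrow, with a median width of 379 bp (quartiles 367 to 526 bp) against 1033 bp (quartiles 408 to 1872 bp) for the 82 without H3K79succ. The summits of the Gcn5 and H3K79succ regions lay a median of 9 bp apart there, against 118 bp at the other 436 shared Gcn5 regions.

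**Figure D2:**
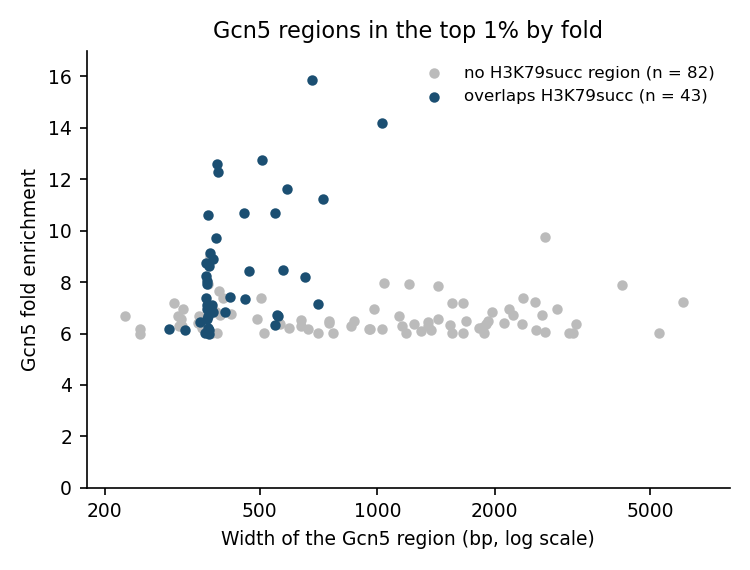
Fold enrichment against width in bp (log axis) for the 125 Gcn5 regions in the top 1% by fold enrichment, each point 1 region, dark where it overlaps an H3K79succ region of U251 cells. The 10 highest points all overlap H3K79succ, and the 43 dark points gather near 379 bp while the 82 light points spread to over 1000 bp.

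The α-KGDH regions were compared with the H3K79succ and Gcn5 lists to ask whether the source of succinyl-CoA sits at the modified histone and at Gcn5. Of the 249 α-KGDH regions, 156 (62.7%, interval 56.3 to 68.7%) overlapped H3K79succ and 40 (16.1%, interval 11.7 to 21.2%) overlapped Gcn5. Circular shifts gave 1.18 and 0.889 regions on average and at most 6 in either case (permutation p = 0.001 for both, 0.001 adjusted), and local moves gave 6.35 and 1.83. By class, 30 α-KGDH regions (12.05%, interval 8.28 to 16.8%) overlapped both, 126 (50.6%) H3K79succ only, 10 (4.02%) Gcn5 only, and 83 (33.3%) neither. Given these 2 shares, 25.1 regions with both are expected if the overlaps are independent (odds ratio 1.98, interval 0.917 to 4.26; two-sided Fisher's exact test, p = 0.108).

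The α-KGDH region of chromosome 20, 2451007 to 2451442 (fold 7.79), and that of chromosome 17, 80231098 to 80231547 (fold 6.67), overlapped both H3K79succ and Gcn5. That of chromosome 6, 31509413 to 31509755 (fold 6.83), overlapped Gcn5 only. The α-KGDH regions of highest fold enrichment, on chromosome 7, 23514269 to 23515407 (fold 8.81) and 25902459 to 25903927 (fold 8.42), overlapped neither. In total, 32 H3K79succ regions overlapped both other lists. The strongest by H3K79succ fold enrichment were chromosome 1, 46767017 to 46768951 (fold 9.63), chromosome 12, 66218817 to 66220471 (fold 9.34), chromosome 1, 45241350 to 45242567 (fold 7.35) and chromosome 9, 136215100 to 136215910 (fold 6.94). They were followed by chromosome 1, 93297984 to 93298577 (fold 6.16), chromosome 10, 103454139 to 103455192 (fold 5.97) and chromosome 3, 134092866 to 134093298 (fold 5.87). The last of the 10 named were chromosome 17, 72200017 to 72200593 (fold 5.71), chromosome 20, 42086546 to 42086920 (fold 5.63) and chromosome 7, 72935479 to 72936380 (fold 5.54). At the region of chromosome 1 that begins at 93297984, Gcn5 had a fold enrichment of 7.36 and α-KGDH of 5.93 within their own lists.

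H3K79succ regions with α-KGDH were stronger and wider than the rest. A wide region meets the rule of 1 shared base pair more easily, and the folds were not compared at matched width. The 155 with α-KGDH had a median H3K79succ fold enrichment of 4.66 against 3.44 in the 16952 without, a difference of 1.22 (permutation p = 1e-05, the smallest 100000 resamples can give), and a median width of 619 bp against 258 bp. The share with α-KGDH was 0.306% in the lowest quintile of H3K79succ fold enrichment and 2.85% in the highest. The α-KGDH overlaps moved in opposite directions at stricter thresholds: with −log10 q of at least 5 in every list, 14 of 43 α-KGDH regions (32.6%) overlapped H3K79succ and 13 (30.2%) overlapped Gcn5. The other lists shrank as well, to 3327 H3K79succ and 976 Gcn5 regions, and no expected overlap is given at these sizes. With a fold enrichment of at least 5 the shares were 17.9% and 32.1% of 28 regions, and without the top 1% of each list the share with both fell to 7.69%.

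H3K79succ in shGcn5 cells was compared with U251 cells to ask whether the mark depends on Gcn5. The shGcn5 list held 270 regions (median width 264 bp, 0.0808 Mb in all), and the U251 list, with 17107, held 63.4 times as many. The Gcn5 level of the shGcn5 line was not analysed here. Of the U251 regions, 192 (1.12%, interval 0.970 to 1.29%) overlapped an shGcn5 region, and of the shGcn5 regions, 198 (73.3%, interval 67.6 to 78.5%) overlapped a U251 region, where circular shifts gave 1.30 on average (permutation p = 0.001, 0.001 adjusted). The strong U251 regions on chromosome 1, 156084548 to 156085866, chromosome 17, 38278581 to 38279747, and chromosome 19, 47613866 to 47615492, were among those also called in shGcn5 cells. Those of chromosome 11, 11268027 to 11268644, and chromosome 20, 49546812 to 49547717, were not. Of the 10 named regions in the H3K79succ, Gcn5 and α-KGDH lists, those on chromosome 1, 46767017 to 46768951, and chromosome 12, 66218817 to 66220471, were also in the shGcn5 list.

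The lists were called at different thresholds, with a lowest −log10 p of 3.03 in U251 and 6.51 in shGcn5 cells. Under the shGcn5 minimum the U251 list still held 7818 regions against 270, a ratio of 29.0; the ratio was 20.4 with −log10 q of at least 5 (3327 and 163 regions) and 14.01 with a fold enrichment of at least 5 (1359 and 97 regions). The share of U251 regions also called in shGcn5 cells was highest in the top quintile of U251 fold enrichment, at 4.02% (134 of 3330, interval 3.38 to 4.75%). From the lowest quintile to the fourth it was 0.334% (12 of 3591), 0.215% (7 of 3262), 0.432% and 0.696%. Of the 100 U251 regions of highest fold enrichment, 20 were called in shGcn5 cells.

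**Figure D3:**
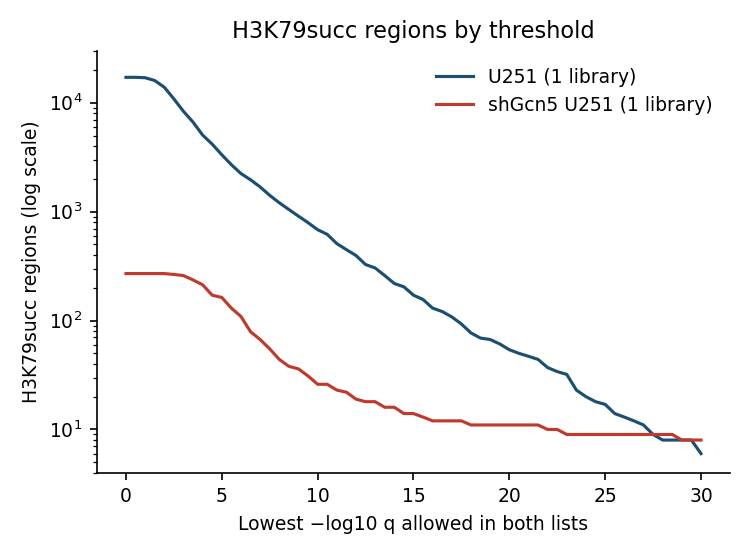
Number of H3K79succ regions (log axis) against the lowest −log10 q allowed in both lists, for the U251 library and the shGcn5 library. The U251 line lies above the shGcn5 line up to a threshold of 27, with 3327 against 163 regions at 5 and 683 against 26 at 10; from 27.5 to 30 the lines meet and cross, with 9 or fewer regions in each list.

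The shGcn5 list also held 72 regions with no overlapping region in the U251 list, although 213 of its 270 regions, against the 198 that overlap, lay within 500 bp of a U251 region. A weaker U251 region under the threshold would not be listed, and the reads at these sites, which would show duplicates or inserted sequence, were not analysed here. The 5 shGcn5 regions of highest fold enrichment lay on chromosome 8, 96345139 to 96345517 (fold 32.4), chromosome 7, 15229590 to 15229987 (fold 26.7), chromosome 15, 25012473 to 25012840 (fold 15.4), chromosome 13, 30409100 to 30409430 (fold 14.01) and chromosome Y, 17081109 to 17081426 (fold 12.8). None of these 5 overlapped a region of any other list. The 72 shGcn5 regions without a U251 partner had a median fold enrichment of 5.45, against 4.72 in the 198 with one (permutation p = 1e-05, the smallest 100000 resamples can give).

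Among H3K79succ regions of U251 cells, 11 of 482 with Gcn5 (2.28%, interval 1.15 to 4.05%) and 181 of 16625 without (1.09%, interval 0.937 to 1.26%) were also called in shGcn5 cells. The odds ratio was 2.12 (interval 1.15 to 3.93; two-sided Fisher's exact test over regions, p = 0.0244), with the higher share among regions with Gcn5. This difference was not past the threshold when regions were stratified by quintile of fold enrichment (Mantel-Haenszel odds ratio 1.84, interval 0.980 to 3.43), and with −log10 q of at least 5 in every list it turned to 0.707, with 1 of 56 regions with Gcn5 called in shGcn5 cells (Fisher's exact test, p = 1). The same split by α-KGDH, made after the values were seen, gave 32 of 155 regions (20.6%, interval 14.6 to 27.9%) with α-KGDH and 160 of 16952 (0.944%, interval 0.804 to 1.10%) without. Its odds ratio was 27.3 (interval 18.0 to 41.5), 12.2 within quintiles of fold enrichment (interval 7.84 to 18.9) and 8.60 within quintiles of fold enrichment and width together (interval 5.54 to 13.4). The highest quintile spans folds of 4.16 to 11.2. The share called in shGcn5 cells was 4.02% in that quintile and 20% among the 100 highest folds. Differences in fold enrichment within that quintile are therefore not removed by the stratification.

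**Figure D4:**
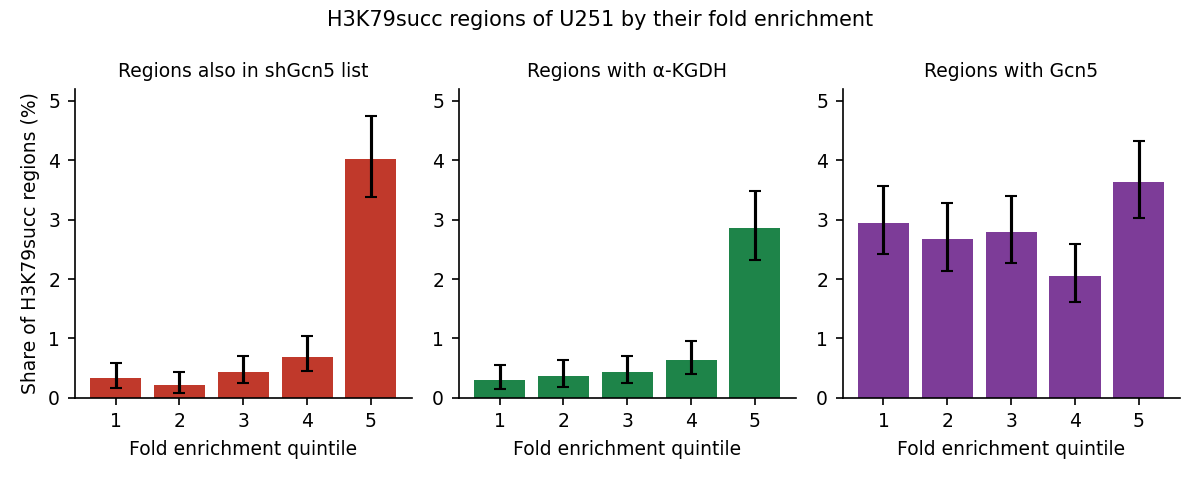
Share of the H3K79succ regions of U251 cells, in percent, that are also in the shGcn5 list, overlap α-KGDH or overlap Gcn5, by quintile of H3K79succ fold enrichment (1 is the lowest, 5 the highest); bars show shares and whiskers 95% exact binomial intervals. The first and second panels reach 4.02% and 2.85% in the highest quintile and stay under 0.7% in the others, while the share with Gcn5 stays between 2.06% and 3.63%.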

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

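The single p-value minimum, the local moves, all settings of the median difference, the top 1% left out for the odds ratio with Gcn5, and the stratified odds ratios with α-KGDH were chosen after seeing the data. The excess over expected overlap kept its direction and permutation p = 0.001 under random placement and local moves for all 12 overlaps run, and the α-KGDH odds ratio stayed above 1 in both stratified forms. Each pair of lists is counted in both directions among the 12. For every other change below the cause was not tested; stricter filters leave fewer regions in both lists of a pair. Leaving rows unmerged moved nothing and keeping chromosomes 1 to 22 and X removed at most 1 region, so neither tests stability. Promoter, start-site and gene-list alternatives were not run without an hg19 annotation. No paired analysis was possible because each group has 1 library. Pileups near 18 fragments limit what a missing overlap shows: a weaker region can stay under the threshold.

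Shares follow in the order H3K79succ with Gcn5, Gcn5 with H3K79succ, α-KGDH with H3K79succ, and shGcn5 with U251. They were 2.13%, 2.91%, 56.2% and 66.3% at 50% overlap; 4.17%, 5.55%, 73.1% and 78.9% within 500 bp; 1.68%, 5.64%, 32.6% and 57.1% at −log10 q of at least 5; 2.06%, 7.38%, 17.9% and 29.9% at a fold of at least 5; and 2.54%, 3.46%, 55.1% and 62.2% without the top 1%. Under one p-value minimum the first 3 of these shares were 1.57%, 2.62% and 52.5%. The share of α-KGDH regions with Gcn5 rose to 30.2% and 32.1% at the q and fold thresholds, and that with both fell to 7.69% without the top 1%. The share of U251 regions also called in shGcn5 cells was 1.46% within 500 bp, 2.49% at the q threshold, 2.06% at the fold threshold, 0.968% without the top 1% and 2.24% under one p-value minimum. The ratio of U251 to shGcn5 regions fell from 63.4 to 20.4, 14.01 and 29.0 at the q, fold and p thresholds.

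The odds ratio of being called in shGcn5 cells, with over without Gcn5, was 1.84 stratified by fold, 2.28 under one p-value minimum (Fisher's exact test, p = 0.0575) and 1.72 without the top 1% (p = 0.201), none past the threshold; 2.29 at 50% overlap (p = 0.0297), past it as in the full lists; and 0.707 at the q threshold, where 1 of 56 regions decides it. The median difference of H3K79succ fold with minus without Gcn5 was 0.0327 at 50% overlap (p = 0.3), -0.0739 within 500 bp (p = 0.0055), 0.391 at the q threshold (p = 0.0036), -0.0838 without the top 1% (p = 0.024) and 0.743 under one p-value minimum (p = 0.0001, the smallest 10000 permutations can give), so no direction holds.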

Other observations

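The tests of threshold, depth, loss confined to regions with Gcn5, immunoprecipitation strength and sites shared by all libraries, and every split by chromosome, α-KGDH overlap of narrow sites, distance to a chromosome's end, run of regions or region width below, were chosen only after the results were seen. Gcn5 regions gathered near chromosome ends: 5091 of 12505 (40.7%, exact binomial interval 39.9 to 41.6%) lay within 5 Mb of the first or last region of their chromosome, against 2326 of 17107 H3K79succ regions (13.6%, interval 13.1 to 14.1%), 44 of 249 α-KGDH regions (17.7%), 34 of 270 shGcn5 regions (12.6%) and 7.94% of the span covered. The odds ratio of Gcn5 against H3K79succ was 4.36 (interval 4.12 to 4.62). Of the 217 Gcn5 regions of 1000 bp or more, 152 (70.0%, interval 63.5 to 76.1%) lay there and 1.38% overlapped H3K79succ. Of the 364 H3K79succ regions of that width, 80 (21.98%, interval 17.8 to 26.6%) lay there. On chromosomes with a short arm that carries few mapped reads, the first region is not at the chromosome's end. Neighbouring Gcn5 regions were also common, since 6252 (50%) lay in runs of at least 3 regions with gaps of at most 10 kb, against 21.0% of H3K79succ regions.

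Chromosome 7 held 42 of the 270 shGcn5 regions (15.6%, interval 11.4 to 20.4%), against 7.06% of the U251 regions, 7.48% of the 7818 U251 regions past the shGcn5 p-value minimum, and 11.6% of the α-KGDH regions. Chromosome 17 held 30 shGcn5 regions (11.1%, interval 7.62 to 15.5%) against 5.93% of the U251 regions. Fisher's exact tests of shGcn5 against U251 regions, run on 21 chromosomes, gave odds ratios of 2.42 for chromosome 7 (adjusted p = 4.39e-05) and 1.98 for chromosome 17 (adjusted p = 0.0116), and past the p-value minimum, where chromosome 17 was not run, 2.28 for chromosome 7 (p = 1.24e-05). These tests compare the regions of 1 library per line, not the lines, and their p-values can be too small, since 11.5% of the shGcn5 regions lay in runs. In the α-KGDH list, 9 runs held 30 regions (12.05%). A run of 4 on chromosome 22, 46468123 to 46471066, overlapped H3K79succ at all 4 regions and the shGcn5 list at 2. Runs of 4 on chromosome 6, 6004377 to 6008506, and of 3 on chromosome 7, 23514269 to 23517863, overlapped no other list. A run of 4 on chromosome 1, 565054 to 569833, also overlapped none, and its background reached 4.85 times the floor, the highest of the 9 runs. No list was filtered for regions of high background or for regions prone to artefacts. These 4 regions therefore count among the 83 α-KGDH regions with neither H3K79succ nor Gcn5, and an artefact there was not excluded. Among the 25 shGcn5 regions of highest fold enrichment, 21 had no U251 partner. The 8 with a fold enrichment of 10 or more overlapped no other list, were 318 to 398 bp wide with pileups of 50 to 161 fragments, and lay at least 29.3 kb from any U251 region. The 5 U251 regions of that fold enrichment had a median width of 1167 bp.

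The shGcn5 list was far shorter than the U251 list. The stricter calling of the shGcn5 list can account for only a part of this. The ratio of regions fell from 63.4 to 29.0 under one p-value minimum, 20.4 at −log10 q of at least 5 and 14.01 at a fold of at least 5. The recovered background floor was 1.04 times that of U251 under the formulas of MACS2. It scales with fragments times fragment length, and fragment lengths were not seen. The floor therefore argues against lower depth only if these lengths were alike. Of the 16915 U251 regions absent from the shGcn5 list, 16444 (97.2%) had no called Gcn5 region, so absence was not confined to regions with one. But 16625 of all 17107 U251 regions had none either. With so many regions absent, this share could hardly have come out otherwise, and it does not test whether loss was tied to Gcn5. Whether regions with Gcn5 were lost more often could not be told apart from even loss in the stratified test (odds ratio of being called 1.84, interval 0.980 to 3.43), while unstratified they were called more often (11 of 482 against 181 of 16625, odds ratio 2.12, interval 1.15 to 3.93). The share called was 12.04 times as high in the highest as in the lowest fold quintile, which a weaker immunoprecipitation and a lower level of the mark could both give, so with 1 library per line an effect of the hairpin remains a hypothesis.

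α-KGDH regions overlapped H3K79succ and Gcn5 far more often than shifted regions. Density of regions on scales above the moves of up to 50 kb does not account for this. The overlap with Gcn5 was 21.8 times that after such moves, and the overlap with H3K79succ 24.55 times. Dense stretches shorter than the moves are scattered by them, so a part played by such stretches stays open. Leaving out the top 1% of each list kept 0.781 of the share with Gcn5, between the bounds set for a few very strong sites and for none, so their part stays open. Binding of α-KGDH at places with H3K79succ or Gcn5 is a hypothesis that may apply to the rest, and sites that enrich with several antibodies were not excluded in these 4 lists.

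The 43 Gcn5 regions in the top 1% by fold enrichment that overlapped H3K79succ in U251 cells were narrow, with summits a median of 9 bp apart. Sites that enrich in any library of these cells stay open: of the 40 strong enough in U251 to pass the shGcn5 minimum, 1 (2.5%, interval 0.0633 to 13.2%) had its H3K79succ region in the shGcn5 list, but so did 2.24% of all U251 regions past that minimum. In the α-KGDH list, from V5-OGDH cells and another antibody, 6 of the 43 (13.95%, interval 5.30 to 27.9%) were present, against 24 of the 436 other shared Gcn5 regions (5.50%; Fisher's exact test over regions, p = 0.042). The recovered background at these sites was 1.28 times the floor, the higher of the medians of both lists. It reports input coverage only if an input of these cells was the caller's control. The control is not given, so excess input coverage stays open. A shared control or preparation of the U251 libraries and joint presence of Gcn5 and the mark also stay open as hypotheses, neither of them tested.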
